A study of Homo sapiens with 3 samples.

How the data were processed

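Total RNA of CD18/HPAF cells stably transfected with a scrambled or an NCOA3 knockdown construct was, per the labels' protocols, amplified, labelled and hybridised in pairs to 3 arrays with 2 colours each. The labels number the pairs 1 to 3 and give Cy5 for the control and Cy3 for the knockdown on every array. Scanner, background correction and normalization are not given in the sources used here.

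The authors deposited a table of log2 ratios per probe and array, and neither the direction of the ratio nor any centring is stated. The log2 scale was read from the values, which included the logarithms of ratios of small whole numbers. The deposited medians were -0.07, 0.11 and -0.15 on arrays 1, 2 and 3, so the arrays had not been centred on their medians. Of 29187 probes, 204, 111 and 702 had no value on arrays 1, 2 and 3, and 36, 33 and 73 stood at 16.61, the logarithm of a round ceiling, which was read as a denominator without signal and treated as missing. That reading was chosen after the data were examined. The values give no spot intensities, so probes near background could not be removed. As a stand-in, a ratio was called whole-number where it lay within 0.0006 (log2) of a quotient of whole numbers up to 10 on any array. The authors' deposited table of genes gave, per the file headers, an unadjusted p-value at or below 0.01 and a linear fold (knockdown over control) per probe. The test, the arrays and the normalization behind it are not given in the sources used here. No column was left unassigned.

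The authors' deposited table was the only source of gene names used here, and the array's own probe annotation was not used. Of its 811 rows, 799 were probes of the value table and 12 were control probes. Of the 799 symbols, 700 were current in the gene table of assembly GRCh38.p14, 78 were synonyms of 1 current symbol and were updated, and 19 matched nothing and were kept as given. A probe whose symbol had been turned into a date and 1 further probe were kept as unnamed features. The gene table served for names and for which genes neighbour each other. The named probes stood for 776 genes, 21 of them with 2 probes, which had the same direction in every case and were averaged. All other probes entered as single unnamed features. Features with a value on all 3 arrays were kept, 28145 in all, of which 771 were named genes.

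The direction was settled by setting each column against the authors' deposited fold over the shared probes. Columns 1 and 2 ran with it and column 3 against it, and column 3 was turned in sign. This choice was made after the data were examined, it uses the authors' list, and the counts were repeated without it. The mean of the 3 log2 ratios was tested against 0 with an intercept fitted by lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because each ratio sets control and knockdown of 1 replicate number on 1 array, the test is paired by construction. The fit was tested on simulated log ratios for 28145 features with the fitted spread. For this comparison, 35.8% of 67 features changed by 2-fold and 95.5% of 66 changed by 4-fold passed the adjusted threshold, and 1.49% of 67 changed by 1.5-fold did.

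A test of 36 gene lists against all genes on the array had been planned with limma's camera and fry. Neither was run, since unlisted members could not be named without the probe annotation and listed members had been selected by the authors' test. In their place, the split into higher and lower among the named members of a list was set against that of the other named genes with Fisher's exact test, two-sided and adjusted over the 6 lists with at least 5 named members. A permutation of the mean log2 ratio over named genes (100000 draws, two-sided) was run beside it. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the plots.

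Named genes followed a rule fixed before the data were examined. For a value table that could be joined to names only through the authors' list, it took NCOA3, the 12 largest and 12 smallest ratios with a symbol in that list, and the listed members of the gene lists. Some genes that the rule takes are not reported here. Alternatives covered centring, scaling, quantile normalization, each replicate left out, single probes, missing values, robust moderation, other thresholds and a test without moderation. Others were added after the data were examined: array 3 not turned, a dye term, the ceiling kept as a value, and removal of features with whole-number ratios.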

Results

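RNA of a pancreatic cancer cell line with a stable knockdown of NCOA3 was compared with RNA of the same line carrying a scrambled construct on 3 arrays with 2 colours each. The line, CD18/HPAF, is an established human ductal adenocarcinoma line, and NCOA3 (also called SRC-3 or AIB1) is a p160 coactivator that nuclear receptors and other transcription factors recruit to activate genes. The cells had been grown for 48 h, and each array paired 1 control culture with 1 knockdown culture, which the labels call biological replicates. The sample descriptions and titles do not say whether the 3 pairs came from separately transfected populations. If each construct had 1 population, a difference between the populations could not be told apart from an effect of the knockdown. The deposited value table held 1 log2 ratio of both dyes per probe and array, with 28983, 29076 and 28485 values on arrays 1, 2 and 3. The second deposited file was the authors' deposited table of 811 rows that passed their test at an unadjusted level of 0.01, with a p-value, a ratio of knockdown over control and a gene symbol. Of the sources used here, only this table paired probes with symbols, and no annotation of the array's probes was used, so genes are named only where they had passed that test. Only 3 arrays were hybridised, and their number limits the precision of every value.

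The direction of the ratio was set from the authors' deposited table, because the labels gave control Cy5 and knockdown Cy3 on all 3 arrays while the columns did not run the same way. Across the 794 listed probes with a value on every array, Pearson's r with the log2 fold of the authors' deposited table was 0.946 for array 1, 0.978 for array 2 and -0.866 for array 3. These correlations were across probes, which are not independent replicates. The sign of array 3 was therefore turned in all values below, so that a positive log2 ratio stands for a higher level in the knockdown. As deposited, NCOA3 itself was at -0.84 and -0.72 on arrays 1 and 2 and at 0.86 on array 3, so that with the labelled dyes, the same on every array, and 1 direction of the ratio, the target could not be lower in the knockdown on all 3 arrays. Results without the turn are given beside those for features at an unadjusted p under 0.01, for listed features and for the signs of the largest and smallest ratios. Counts for gene groups are given with the turn only.

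**Figure D1:**
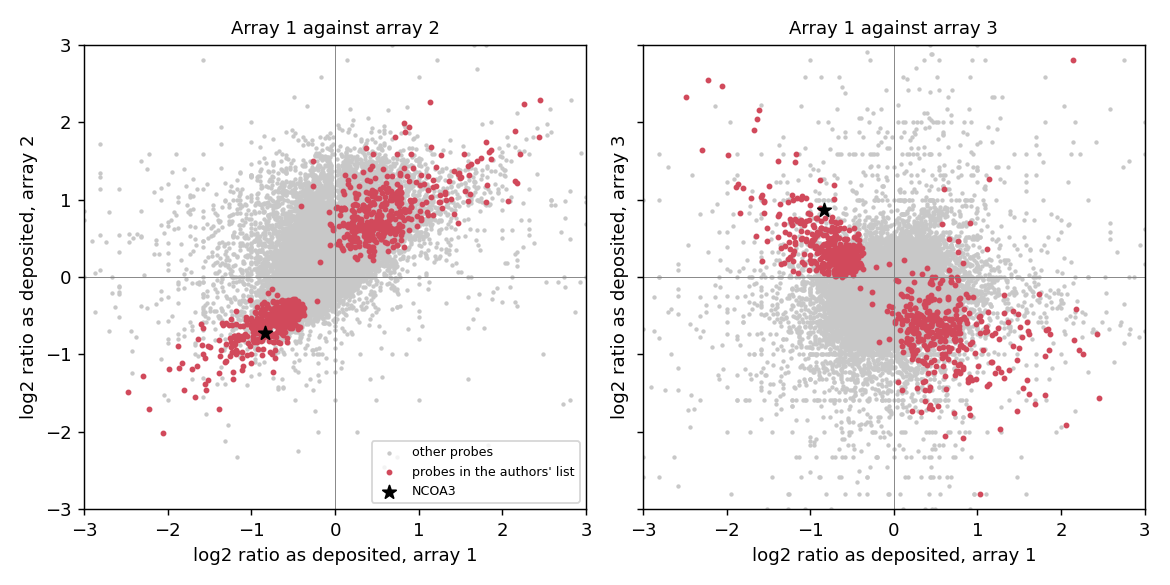
Log2 ratios as deposited on array 1 (x axis) against array 2 (left, y axis) and array 3 (right, y axis). Each point is a probe with a value on all arrays; red points are the 794 probes of the authors' list, grey points the other 27372, and the star is NCOA3; the axes leave out 95 probes with a value beyond 3. Listed probes lie along the rising diagonal for array 2 (r = 0.915) and along the falling one for array 3 (r = -0.769).

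The first question was whether the target itself was lower in the knockdown. With array 3 turned, NCOA3 was lower on all 3 arrays, with a mean log2 ratio of -0.81 ± 0.08 (SD, n = 3), which is a ratio of 0.572. In the authors' deposited table its ratio was 0.567, with a p-value of 0.0012. Over all features tested here the difference did not pass the threshold (limma, adjusted p = 0.35). Without the turn of array 3 the mean was -0.23. NCOA3 is among the listed probes from which the turn was chosen. Its sign on array 3 and its small SD are therefore no independent check of the knockdown. The series title also names the mucins MUC1 and MUC4, membrane glycoproteins of pancreatic tumours. No mucin symbol occurred in the authors' deposited table, and MUC1 and MUC4 could not be read from the value table here, because no annotation of its other probes was used.

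The main comparison asked which genes differed between knockdown and control. The genes lower in the knockdown were led by LOXL2, an enzyme that crosslinks collagen in the matrix, at -2.18 ± 0.25 (SD, n = 3). FERMT2 (kindlin-2), an integrin adaptor at adhesion plaques, was at -2.10 ± 0.53 (SD, n = 3), and CAV1, the main protein of caveolae, at -1.71 ± 0.17 (SD, n = 3). The receptor tyrosine kinase AXL was at -1.24 ± 0.31 (SD, n = 3) and LIFR, the receptor of leukaemia inhibitory factor, at -1.41 ± 0.39 (SD, n = 3). CXCL8, the neutrophil chemokine also called interleukin 8, was at -1.58 ± 0.40 (SD, n = 3). The metalloreductase gene STEAP4 was at -1.53 ± 0.16 (SD, n = 3). Further genes among the 12 smallest ratios were PAK6-AS1 (C15orf56 in the file) at -1.74, RASSF8 at -1.32 and PRDM8 at -1.26. ASAP1, a GTPase-activating protein for ARF proteins, was at -1.08 as the mean of a probe at -1.47, which gave it its rank, and another at -0.69. With array 3 turned, all 12 were lower on all 3 arrays, while as deposited array 3 opposed arrays 1 and 2 for each of them. The turn was chosen from listed probes, so this agreement is not an independent check. In the authors' deposited table the ratio was 0.241 for LOXL2, 0.289 for FERMT2 and 0.296 for CAV1.

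Among the genes higher in the knockdown, the tetraspan membrane protein gene CLRN3 was at 2.10 ± 0.47 (SD, n = 3). CDH17, the liver-intestine cadherin, was at 1.61 ± 0.10 (SD, n = 3), with closely similar values on the 3 arrays. The chaperonin subunits CCT2 and CCT7 were at 1.63 ± 0.70 and 1.48 ± 0.48 (SD, n = 3). ALDH3A1, an aldehyde dehydrogenase, was at 1.58 ± 0.63 (SD, n = 3). The proteasome ATPase PSMC2 was at 1.42 ± 0.46 (SD, n = 3), and CLDN18, a tight junction claudin of stomach epithelium, at 1.04 ± 0.75 (SD, n = 3). WBP1L (C10orf26 in the file), FIBP and PRR13 were at 1.83, 1.62 and 1.46. TRIM13 had the highest ratio of the authors' deposited table, 4.35, but lacked a value on at least 1 array and was not tested here. With array 3 turned, the other 11 of the 12 genes were higher on all 3 arrays, while as deposited array 3 opposed arrays 1 and 2 for each of them. This agreement too follows from the choice of sign. Of these 11 genes, 3 carried a ratio of small whole numbers on 1 or more arrays, against 0 of the 12 smallest ratios and 18.7% of all features. Dim spots can give such ratios, but there were no intensities to check this.

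**Figure D2:**
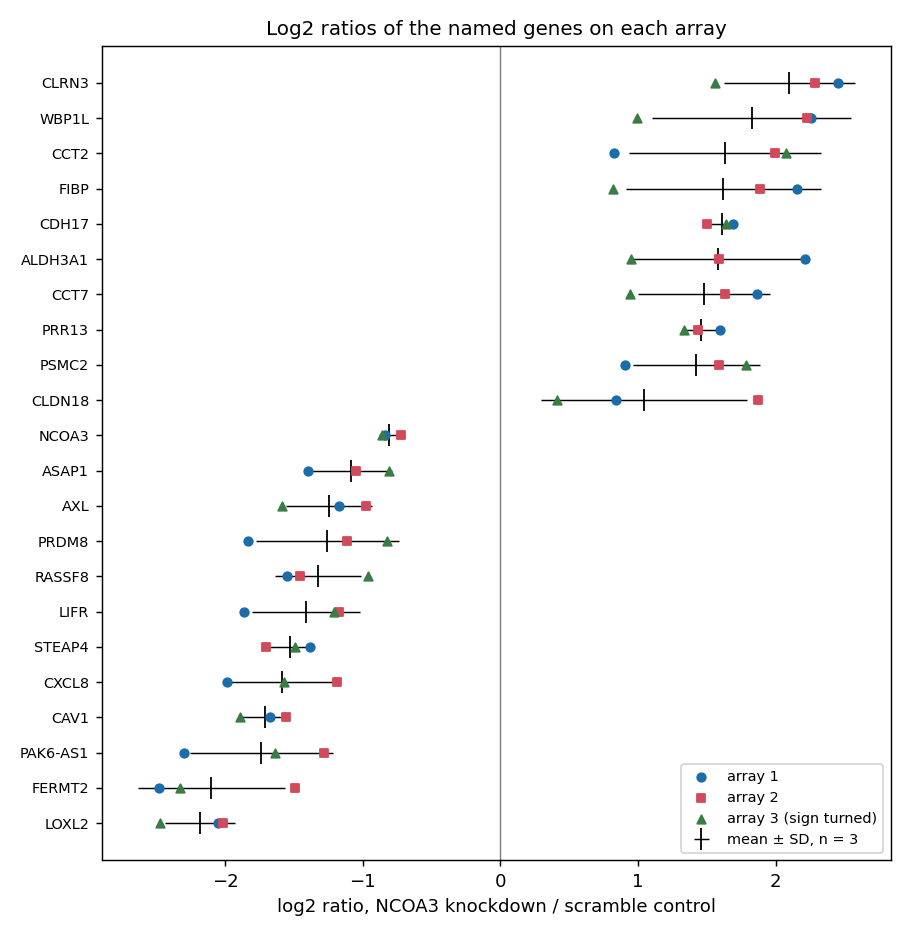
Log2 ratio of NCOA3 knockdown over scramble control (x axis) for NCOA3 and for genes among the 12 largest and 12 smallest ratios in the authors' list (y axis). Symbols are single arrays, with array 3 turned in sign, and the vertical tick and line are the mean and SD of 3 arrays; TRIM13 is left out for lack of a value on every array, and genes not reported here are left out too. LOXL2 lies lowest at a mean of -2.18 and CLRN3 highest at 2.10.

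No feature of the 28145 tested passed an adjusted p of 0.05 (limma, lowest adjusted p = 0.35), against 2858 at an unadjusted p under 0.05, where chance alone would give 1407. That count was 1092, under the chance number, without replicate 2, and 4359 without replicate 3. At an unadjusted p under 0.01 there were 735 features, 561 higher and 174 lower, where chance would give 281. The share higher depended on the setting. It was 76.3% of these 735 features, which were called with array 3 turned and no centring. With each array centred on its median, 896 features were called, 553 higher and 343 lower, a share of 61.7%. The number higher was similar and the number lower rose, but the 2 sets were not the same features, since 607 features were in both. The median log2 ratio of all features was 0.064 before centring and 0.004 after it, so part of the upward split may be an offset of whole arrays. That was not tested. Without replicate 1 the split was 775 higher and 68 lower, and without replicate 2 the count was 280, 161 higher and 119 lower. Without the turn of array 3 there were 420 features, 217 higher and 203 lower. A dye term on median-centred arrays, chosen after the data were examined, gave 69 features past the adjusted threshold.

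The authors' deposited table held 799 probes of the value table, 389 higher and 410 lower in the knockdown, and 12 rows of control probes. Of these probes, 46 were at least 2-fold higher and 35 at least 2-fold lower in the authors' deposited table. Chance would give about 292 of the 29187 probes at that level, and the Benjamini-Hochberg estimate over all probes at the last row of the authors' deposited table was 0.365. All 773 listed features tested here had the direction of the authors' deposited table, and 742 had the same sign on all 3 arrays, against 17 without the turn of array 3. The choice of sign rests on these same probes, so neither count is an independent check. Of the 773 features with the lowest p in the limma fit, 339 were in the authors' list, against 8 without the turn of array 3. The turn was chosen from that list, so this rise is no independent check either. The overlap was 168, 238 and 213 without replicates 1, 2 and 3, and 166 in a test without moderation.

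The gene groups below had been listed before the data were examined, and a member could be counted only if the authors' list named it, so that counts of members past a threshold are not independent evidence. The question was whether the named members of a group leaned to one direction more than the other named genes, of which 379 of 771 were higher.

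All 5 listed members of the chemokine and cytokine group, of 30 on it, were lower in the knockdown, with a mean log2 ratio of -1.06 ± 0.28 (SD over arrays, n = 3). They were the neutrophil chemokines CXCL8, CXCL1 at -1.25, CXCL5 at -0.89 and CXCL2 at -0.75, and the lymphocyte chemokine CCL20 at -0.80. All 7 listed NF-kB target genes, of 18 in the group, were lower too, with a mean of -1.04 ± 0.26 (SD over arrays, n = 3), and 3 of them are chemokines already named. The other members were BIRC3, an inhibitor of apoptosis, at -1.13, TNFAIP2 at -1.01, the iron-sequestering protein LCN2 at -0.82 and the NF-kB regulator NFKBIZ at -0.65. The cytokines IL36G and IL36B, which belong to neither group and were picked after their values were seen, were higher at 0.59 and 0.41. By direction alone neither group passed Fisher's exact test, two-sided and adjusted over the 6 groups with at least 5 named members (adjusted p = 0.124 for the chemokines and 0.0918 for the NF-kB targets). By the mean log2 ratio, tested by permutation over the named genes, both passed (adjusted p = 0.00093 and 0.00048), a test that was chosen after the data were examined and treats genes as independent. Adjusted over the list alone, 5 of 5 chemokine and 7 of 7 NF-kB genes were past 0.05, against 0 over all features.

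The group of immediate early genes, which growth signals switch on within minutes, and AP-1 genes held 22 genes. All 5 listed members had a mean log2 ratio below 0. The MAP kinase phosphatases DUSP5 and DUSP1 were at -1.07 and -0.48, the transcription factors KLF2 and KLF4 at -1.08 and -0.32, and the AP-1 subunit FOSL1 at -0.67. KLF4 was not lower on array 3, where it was at 0.007. The group mean was -0.72 ± 0.22 (SD over arrays, n = 3). Fisher's exact test did not separate the group from other named genes (adjusted p = 0.124), the permutation of the mean did (adjusted p = 0.0306), and with groups of 3 members admitted it no longer did (adjusted p = 0.0544). Adjusted over the list alone, 4 of 5 were past 0.05, against 0 over all features.

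Of 5 listed matrix proteases, PLAU, the urokinase that activates plasminogen, was at -0.94, MMP7 at -0.80, CTSL at -0.48 and ADAM9 at -0.40, while the membrane protease MMP15 was higher at 0.41. The direction did not depart from that of other named genes (Fisher's exact test, adjusted p = 0.561, and permutation of the mean, adjusted p = 0.195). Adjusted over the list alone, 5 of 5 were past 0.05, against 0 over all features. All 4 listed laminin and integrin genes were lower, among them the laminin chains LAMA3 at -0.48 and LAMB3 at -0.49 and the integrin chain ITGAV at -0.44. The TGF-beta group held TGFBI at -0.64, CCN2 at -0.95 and CCN1 at -0.85, all lower. These groups had under 5 named members, and with groups of 3 members admitted neither passed (laminins and integrins, adjusted p = 0.342 by Fisher's exact test and 0.28 by permutation of the mean, and TGF-beta, adjusted p = 0.548 and 0.0909). Adjusted over the list alone, 2 of 4 laminin and integrin genes and 3 of 3 TGF-beta genes were past 0.05, against 0 over all features. Other matrix genes of the authors' list, outside these groups and picked after their values were seen, went both ways, with NPNT at 1.17, COMP at 0.85, HTRA1 at 0.79, FBN1 at 0.69 and TNC at 0.53, and with LOXL2 as above, COL13A1 at -0.62, NTN4 at -0.54, PLOD2 at -0.46 and PCOLCE2 at -0.42.

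Epithelial and tumour marker genes went both ways. The adhesion molecule EPCAM and the epithelial transcription factor GRHL2 were higher at 0.76 and 1.25, while the junction genes CLDN3, TJP1 and DSG2 were lower at -0.52, -0.40 and -0.35 (Fisher's exact test, adjusted p = 1, and permutation of the mean, adjusted p = 0.78). The mesenchymal intermediate filament VIM, the only listed gene of its group, was lower at -1.46 ± 0.79 (SD, n = 3). Among tumour markers CLDN18, LYZ, CEACAM7 and S100A14 were higher, the last 3 at 1.05, 0.74 and 0.58, and CEACAM6, LCN2 and S100A2 were lower, CEACAM6 at -0.87 and S100A2 at -0.42 (Fisher's exact test, adjusted p = 0.865, and permutation of the mean, adjusted p = 0.759). Adjusted over the list alone, 5 of 5 epithelial and 7 of 7 marker genes were past 0.05, against 0 over all features.

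Smaller groups are given as values. Among glycosylation enzymes, the mucin-type enzymes GCNT3 and B3GNT3 were higher at 0.59 and 0.79, and FUT8, which adds core fucose to N-glycans, and GCNT2 were lower at -0.999 and -0.41. Of the retinoid group, RARRES1 and TGM2 were lower at -1.20 and -0.78 and LRAT, which esterifies retinol, was higher at 1.07. In cholesterol synthesis FDPS was higher at 1.23, and INSIG1, MSMO1 and SC5D were lower at -0.57, -0.47 and -0.36. The coactivator partner KAT2B was at -0.52, IGFBP3 and IRS1 of insulin-like growth factor signalling at -1.04 and -0.53, the apoptosis genes CASP1 and BIRC2 at -0.65 and -0.49, the lipid genes LPIN1 and ELOVL6 at -0.54 and -0.42, and the oxidative stress genes GCLM and SLC7A11 at -0.62 and -0.38. Of the p53 targets ZMAT3 was at 0.73 and RRM2B at -0.41. Groups with 1 listed gene held the nuclear receptor HNF4A at 0.48, IRF1 at -0.46, TYMS at -0.42, UBE2E1 at -0.37, CA9 at 0.92, RPL22 at 0.59, CYCS at 0.58 and the histone gene H2AC6 at 0.65. Markers of other cell types were represented by CTRC of acinar cells at 0.62, LUM of fibroblasts at 0.89 and LYZ, which the leukocyte and the tumour marker groups share. CTRC was at 0.757, 1.109 and 0 on arrays 1, 2 and 3, and had a ratio of small whole numbers on 1 array. The mucin, mitosis, endoplasmic reticulum stress, heat shock, WNT, duct and endocrine groups, 7 of the 36, had no listed gene.

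**Figure D3:**
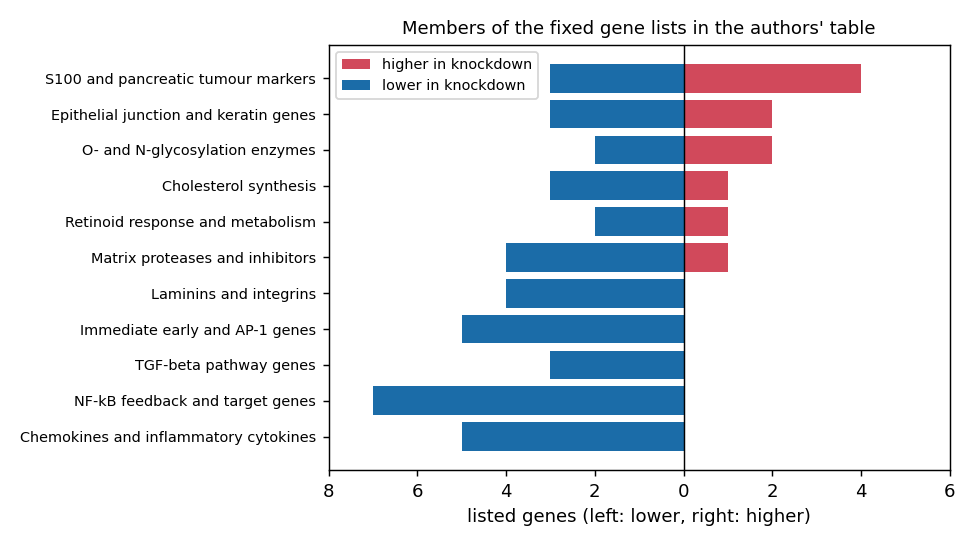
Number of genes of each group fixed before the data were examined that the authors' list names and that have a value on every array (x axis, lower in the knockdown to the left, higher to the right), for groups (y axis) with at least 3 such genes. All 7 NF-kB targets and all 5 chemokine and 5 immediate early genes lie on the lower side.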

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

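All tests in this part were chosen after the values they concern had been seen, except the comparison of whole-number ratios between probes listed higher and lower, whose criterion was tightened after its result was seen.

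Data outside the main comparison carried a signal: 12 rows of the authors' deposited table were control probes, of 4 kinds, and all 12 had a ratio above 1, from 1.37 to 2.06 with a median of 1.65. Repeated rows of 1 control probe are not independent. In the deposited values the knockdown channel was not brighter for all probes. The median log2 ratio of all features was 0.064 with array 3 turned and -0.038 without the turn, and 410 listed probes were lower. These values cannot exclude a brighter channel before normalization. The normalization is not given, and it may have removed such a difference from the other probes but not from the controls. Dim spots with ratios drifting upward also stay open as a candidate explanation. Among listed probes, 17.7% of those higher and 3.90% of those lower had a ratio of small whole numbers, a difference of 13.8 percentage points (95% interval 9.60 to 18.1), where positions shifted off those ratios gave 5.40% and 6.83%, and the share over all features was 18.7%. The control probes themselves had no values to test. No biological explanation was tested for control probes.

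Array 3 opposed arrays 1 and 2 over the listed probes. A column that simply holds the inverted ratio of the same dyes is argued against, because over the 27372 other probes arrays 1 and 3 had r = 0.152 and arrays 2 and 3 had r = -0.047, where the mirror of arrays 1 and 2 (r = 0.371) would lie clearly below 0. Selection of the list is argued against as well, since 69% of the 100 probes farthest from the median on arrays 1 and 2 opposed them on array 3 (exact 95% interval 59.0 to 77.9). An exchange of RNAs or dyes on array 3 that the labels leave out stays open. NCOA3 at 0.86 on that array as deposited goes the way such an exchange would need, but NCOA3 is itself among the listed probes and so cannot decide it. A real difference of the third pair of cultures was not tested.

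The 735 features at an unadjusted p under 0.01 were counted with array 3 turned, and the 4 possible sign patterns of 3 arrays are too few for a share under 0.05. Of the patterns, 1 gave as many features, the one used. The others gave 420 with no array turned, 252 with array 2 turned and 70 with array 1 turned. The counts of 252 and 70 lie under the chance number of 281, which is therefore only a rough guide for the 735. Of the 407 such features outside the authors' list, 373 were higher in the knockdown, and 48.2% had a ratio of small whole numbers, against 1.97% at positions shifted off those ratios.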

How the results depend on the processing

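The turn of array 3, the dye term, the ceiling, the removal of whole-number ratios, the permutation test and groups of 3 members were chosen after the data were examined. The test is paired by construction. Beyond it, no paired analysis was possible because each ratio already holds both samples of a replicate number. No feature passed an adjusted p of 0.05 in limma under any alternative except a dye term on median-centred arrays, which gave 69 (of the 69, 46 were higher, 12 were in the authors' list and 44 had a whole-number ratio). An unadjusted threshold gave 735. That count was 172 with a log2 ratio of at least 1 besides, 480 in a test without moderation, 420 with array 3 not turned and 1522 with the dye term on centred arrays, and leaving out each replicate gave 280 to 843. It lay within 1.5 times of 735 under all other alternatives run. NCOA3 was below 0 under all 9 alternatives, from -0.87 to -0.23 (array 3 not turned), with adjusted p from 0.219 to 1. None of the groups fixed before the data were examined passed by direction under any scaling, left-out replicate or probe setting, and 3 passed in the permutation of the mean. Of the features with the lowest p, 339 were in the authors' list, 68 counting only members with at least a 2-fold ratio, of which there were 79, fewer by construction. Of 1227 values of the other 137 named genes under alternatives, 1222 kept their direction. ACTC1 was between -0.11 and 0.31 with 1 replicate left out, below 0 without replicate 2, and with array 3 not turned HNF4A was at -0.028, RPL22 at -0.013, TMPRSS15 at -0.006 and SRSF1 at -0.046. Where a value moved, the cause was not tested beyond the fewer arrays or features the alternative leaves. The planned filter on dim probes and the list tests with camera and fry were not run, for lack of intensities and of names.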

Other observations

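The 4 gene groups in this part were put together after the authors' list had been read, so their tests describe that list and are hypotheses. Members that the authors' list does not name could not be read. The chromosome test was also chosen after the data were examined, and the neighbour test was set before its result was seen.

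Of 36 genes of the intestinal brush border and of enterocytes, the 14 listed ones with a value on every array were all higher in the knockdown. Their mean log2 ratio was 1.06 ± 0.10 (SD over arrays, n = 3). They included CDH17, the cytoskeletal proteins VIL1 at 0.94 and MYO1A at 1.37, and the microvillus linkage proteins CDHR2 at 0.81, USH1C at 0.82 and ANKS4B at 1.23. The surface antigen GPA33 was at 1.07, the transporters SLC15A1 and SLC7A9 at 1.39 and 1.60, the mRNA editing enzyme APOBEC1 and its partner A1CF at 1.65 and 0.84, FABP6 at 0.56, HNF4A at 0.48 and TMPRSS15 at 0.47. Fisher's exact test of the direction against the other named genes gave an adjusted p of 0.00017 over the 4 groups. MEP1B, a listed member without a value on every array, was not tested, and its ratio in the authors' deposited table was 1.55. The hypothesis that an intestinal gene programme was higher in these knockdown cells is consistent with that split, but the group was found on the same data.

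Of 49 genes that YAP and TAZ are known to activate, only 6 were listed, and all 6 were lower, with a mean of -0.92 ± 0.18 (SD over arrays, n = 3). They were AXL, ASAP1, CCN1, CCN2, TGM2 and GAS6, the last at -0.58 (Fisher's exact test, adjusted p = 0.041). Of 41 actin cytoskeleton and adhesion plaque genes, 16 were listed. Of these, 13 were lower, among them FERMT2, CAV1, SVIL at -0.88 and VCL at -0.51, and 3 were higher, ZYX at 0.61, LIMS2 at 0.56 and ACTC1 at 0.15 ± 0.45 (SD, n = 3). That split had an adjusted p of 0.0405 by Fisher's exact test. WWTR1, which encodes TAZ itself and was picked after its value was seen, was lower at -0.67. Of 56 RNA-binding and splicing genes, 20 were listed. Of these, 14 were higher, among them FUBP1 at 1.42, PABPC4 at 1.38 and SYNCRIP at 1.09, and 6 were lower. The split did not pass by direction (Fisher's exact test, adjusted p = 0.0705) but did by the permutation of the mean (adjusted p = 0.0231).

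Listed genes lying next to each other, with at most 2 genes between them, shared their direction in 66 of 103 pairs, where shuffled directions gave 51.5 on average (permutation p = 0.0027, one-sided). Without pairs whose symbols share their first 3 letters, which leaves 2 pairs of the chemokine cluster in, 56 of 90 pairs did, where shuffling gave 45.0 (permutation p = 0.0132). The share of genes higher differed between whole chromosomes (permutation p = 0.0017), and without genes of whole-number ratios it still did (permutation p = 0.0022). Such a lean would itself raise the number of neighbours that share their direction. The neighbour test therefore does not show an effect of adjacency beyond it. Chromosome 16 stood apart, with 21 listed genes higher and 4 lower (Fisher's exact test, adjusted p = 0.00748 over 23 chromosomes), and no other chromosome passed. Chromosome 19 had 22 higher and 9 lower, chromosome 17 had 16 and 7, chromosome 18 had 1 and 8, and X had 8 and 19. A difference in chromosome copy number between the knockdown and control populations could give such a lean, and so could a bias with GC content, since chromosomes 16, 17 and 19 are rich in GC and chromosome 18 and X are poorer. No genome sequence was used here, so the 2 were not told apart.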
